A study of Mus musculus with 9 samples.

How the data were processed

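RNA was sequenced from mouse brain samples that the labels describe as oligodendrocytes. There were 3 groups of 3 samples: wild-type (WT) mice given placebo, mice of the genotype labelled TG given placebo, and TG mice given NM-101. Per the labels' protocols, RNA was extracted with a kit for fixed, paraffin-embedded material and libraries were made with a QuantSeq kit, which reads transcripts from the 3' end. The submitters' processing notes name Bowtie2 and the genome build mm10. The program that counted or normalized the reads, its version and the annotation are not given in the sources used here.

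The authors deposited 1 table of 33299 RefSeq transcripts by 9 samples, and the table mixes 2 units. The 3 WT columns hold whole-number counts per transcript as deposited by the authors, with totals of 10612290, 14041951 and 11774367. The 6 TG columns hold deposited log2 values with 3 decimals, although the table is named as raw counts. Over 13583 transcripts, the TG values turned back to a linear scale rose with the WT CPM (slope 0.972 on log2 scales) and fell with transcript length (slope -0.869). They are therefore treated here as log2(FPKM + 1), a reading that comes from the values and not from the labels. In transcripts of 2500 to 6000 bases that are the only one of their gene, the low TG values lay in steps, as whole reads divided by length would. Between 84.4% and 87.9% of them lay within 0.2 of a step from a whole number. The steps imply 10220000, 12900000 and 11960000 reads in the TG placebo samples, and 12690000, 11790000 and 9130000 in the TG NM-101 samples. The same procedure on the WT columns gave 10620000, 14040000 and 11780000. That result had to return the WT totals, because the WT values were scaled by the same totals and lengths. It does not check the TG depths.

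The design fixed before the data were examined was a count model over all 9 samples. The units did not allow it, so the main test was replaced by limma on the 6 TG samples, a choice made after seeing the data. Transcript values were returned to the linear scale, summed per gene symbol and written again as log2(value + 1), so the pseudocount was 1. Symbols came from a RefSeq gene table of the assembly GRCm38.p6, which named 32394 transcripts. The other 905 kept their identifiers, which gave 23798 genes. Genes with a mean log2 value of at least 1 over the 6 samples were tested, 12699 in all. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a variance trend and robust shrinkage. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

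Of 25 gene lists fixed before the data were examined, 23 had at least 5 tested members. They were tested with camera, a competitive test of limma, at a preset correlation between genes of 0.01. The test was repeated with the correlation estimated per list, and fry was run beside it. Of the other lists, the one of mitochondrially encoded genes had 0 tested members and the one of blood cell genes had 1.

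Because the WT counts and the TG values were normalized separately, no test was made between them. For description, the WT counts were divided by library size and by transcript length from GENCODE M21 and written as log2(RPKM + 1), which gave 12410 genes with a length for every transcript and a mean of at least 1 over the 9 samples. A list's median difference was placed among the medians of 10000 random lists matched on mean level (10 bins) and length (5 bins). A list was counted as outside when its percentile was under 2.5 or over 97.5. Random members were drawn gene by gene, so the matched range does not allow for correlation between the members of a list. On simulated values with 1 list shifted by 0.3, that list was outside and so was 1 of 22 others. Genes varied independently in those values too.

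The genes named follow a rule written before the data were examined. A fixed set that includes Mbp, Olig2 and Tlr2 is always given. Among genes past the threshold whose groups do not overlap, the 6 with the largest positive and the 6 with the largest negative change are named. For each list called, the 3 members with the smallest p-values are named. Predicted loci are counted and not named. Some genes that the rule names are not reported here. The other called genes, and Malat1, Meg3, Ttr, Snap25 and Filip1l, were named after their values were seen.

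The gene test was run on simulated libraries with the means and spreads of the 12664 genes above 0 in all 6 samples, with 5 simulations for TG NM-101 against TG placebo. Of the genes changed by 1 on the log2 scale it recovered 63.2%, and of those changed by 0.5 it recovered 14.6%. Among 61734 tests of unchanged genes, 20 were called. These simulated genes varied independently, which real genes did not. A list shifted by 0.3 was called in 5 of 5 simulations with the preset correlation and in 4 of 5 with the estimated one. Alternatives to scaling, filter, pseudocount, weights and feature were tried, and each sample was left out in turn.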

Results

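The data comprised 9 libraries from mouse brain, with 3 WT placebo, 3 TG placebo and 3 TG NM-101 samples. The series title names alpha-synuclein derived from neurons and its effects in oligodendrocytes, the cells that make myelin. WT library totals ran from 10612290 to 14041951 counts, and the depth of the TG libraries, read only from steps in their values, ran from 9130000 to 12900000 reads. Neuronal transcripts were abundant in libraries labelled as oligodendrocytes. In the TG placebo group the median level of 25 neuronal genes was 7.58 on the log2(FPKM + 1) scale, against 4.70 for 38 genes of myelin and mature oligodendrocytes. The synaptic gene Snap25 stood between 9.96 and 10.27 in each TG placebo library, and the myelin gene Mbp at a mean of 10.51. The 2 lists hold different genes, so their medians do not compare the content of cell types. The values also fell with transcript length although the kit reads the 3' end, so levels of different genes depend on their length. By library the myelin median was 5.63, 4.36 and 4.20.

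The comparison of TG NM-101 with TG placebo asked what NM-101 changed in the TG genotype. At the threshold, 13 genes were higher under NM-101. The largest rise was in Mt2, a metallothionein that binds zinc and copper, from 9.45 ± 0.27 to 10.47 ± 0.10 (SD, n = 3), a 2.02-fold change with a limma adjusted p of 0.0439. Pou3f1, a POU-domain transcription factor, went from 4.33 ± 0.19 to 5.27 ± 0.09, and Sox9, a transcription factor of astrocytes and glial progenitors, from 3.82 ± 0.10 to 4.59 ± 0.04 (SD, n = 3). Their limma adjusted p was 0.0425 for both. Fam107a was 1.80-fold higher, with an adjusted p of 0.0439 from the same fit. In GRCm38, Mt2 lies on chromosome 8 from 94172618 to 94173567, Pou3f1 on chromosome 4 from 124657646 to 124660655, and Sox9 on chromosome 11 from 112782210 to 112787757.

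Ribosomal genes made up much of the remainder. Rps14 rose 1.76-fold and Rps26 1.72-fold, each with a limma adjusted p of 0.0486, and Rps27l rose 1.67-fold with an adjusted p of 0.0425. Rps27rt (1.91-fold), Rpl14-ps1 (1.87-fold) and Rpl34-ps1 (1.78-fold) are near copies of other ribosomal genes, so reads assigned to them are uncertain. Cops9, a subunit of the COP9 signalosome, rose 1.76-fold. Atp5mpl, a small subunit of ATP synthase, rose 1.61-fold, and Gng10, a G protein gamma subunit, 1.54-fold. All of these genes had higher values in each NM-101 sample than in any placebo sample.

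**Figure D1:**
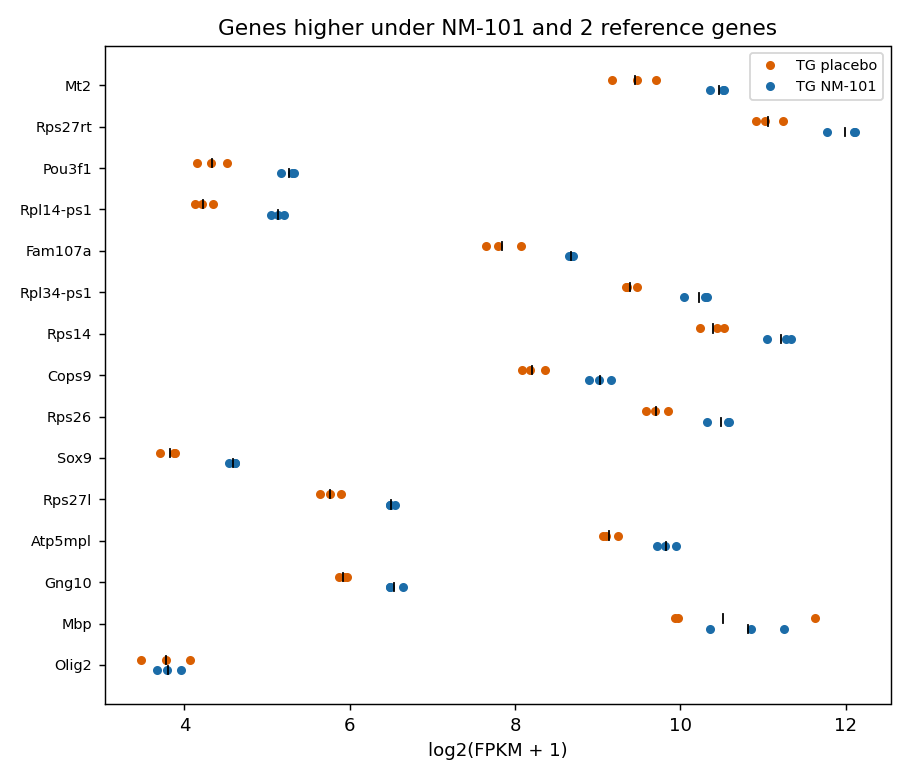
Each point is 1 sample's log2(FPKM + 1) value for a gene, TG placebo in orange and TG NM-101 in blue, and the black ticks are group means. The 13 genes called higher under NM-101 separate the groups, with Mt2 at 9.45 against 10.47, while Mbp spreads widely among the TG placebo samples.

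The other 4 calls were genes listed at 0 in all 3 NM-101 libraries. Lars2, annotated as the mitochondrial leucyl-tRNA synthetase, stood at 12.74, 10.12 and 11.34 in the TG placebo libraries. In the WT libraries it had 153046, 229501 and 138265 counts. These were the highest counts of any transcript in each WT library, at 1.44%, 1.63% and 1.17% of the total. The 12.74 was likewise the highest value of TG placebo replicate 1. Whether all reads assigned to Lars2 come from its mRNA was not examined. Zc3h7a (2.72, 3.56 and 3.68), Cmss1 (2.87, 2.90 and 3.34) and Rnu12, the U12 small nuclear RNA (3.02, 3.36 and 3.51), were likewise above 0 in every TG placebo library. Rnu12 had 0 counts in each WT library, while Zc3h7a and Cmss1 were counted in all of them. A 0 in a table without counts can be a missing estimate, so no fold change is given. Lars2 lies on chromosome 9 from 123366927 to 123462675, and Cmss1 on chromosome 16 from 57301999 to 57606867. Filip1l, which overlaps Cmss1, was also at 0 in all NM-101 libraries, and had 0.76, 0.70 and 1.09 in the placebo ones.

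In total 17 of 12699 genes passed, 13 higher and 4 lower, with 1355 higher and 529 lower at an unadjusted p under 0.05. Groups did not overlap for 19.6% of genes, against 10% by chance. The calls depended on the setting. Without the genes at 0 in any sample, 0 of 12664 passed in limma, with 1894 at an unadjusted p under 0.05. Median-ratio scaling left 4 calls (1 higher, 3 lower). Leaving out 1 sample gave 2263 calls (1222 higher, 1041 lower) without TG placebo replicate 1 and between 2 and 5 without any other sample. The fit without replicate 1 set NM-101 against replicates 2 and 3 alone, which were high in nuclear RNA. Its lower calls included Malat1 (-1.80) and Meg3 (-2.99). The count of 2263 therefore cannot be read as an NM-101 effect that replicate 1 hid.

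Among the 23 lists tested, cytoplasmic ribosomal protein genes had the largest median difference and the smallest camera p-value at the preset correlation. All 46 measured members were higher under NM-101, with a median log2 difference of 0.45, and camera gave an adjusted p of 6.32e-28. The adjusted p was 0.536 with an estimated correlation of 0.74 between members. Adjusted over the list alone, 45 members passed, against 1 over all genes tested. Rps14 and Rps24 were among the members with the smallest p-values, with differences of 0.82 and 0.61. Genes of oxidative phosphorylation had a median of 0.22 (39 of 40 higher, camera adjusted p = 1.12e-08), and the adjusted p was 0.808 with an estimated correlation. Of these, 9 passed when adjusted over the list alone and 0 over all genes. Cox6c was at 0.54, Ndufb8 at 0.46 and Ndufa4 at 0.47. For this pair of groups the list was not set against random lists matched on level and length. For NM-101 minus WT its median of 0.16 lay inside the range of matched lists (0.11 to 0.38).

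Markers of astrocytes and microglia were also higher on balance. The astrocyte list had a median of 0.28, with 23 of 25 members higher (camera adjusted p = 4.76e-07; adjusted p = 0.439 with an estimated correlation). Sox9 passed over all genes and 8 members passed adjusted over the list alone. Slc1a2, the main glutamate transporter of astrocytes, differed by 0.68 with a limma adjusted p of 0.0561, and the tight-junction gene Cldn10 by 0.45. The microglial list had a median of 0.30, with 23 of 25 members higher (camera adjusted p = 7.45e-06; adjusted p = 0.439 with an estimated correlation). Adjusted over the list alone 9 members passed, and over all genes 0. Gpr34 differed by 0.67 and the complement gene C1qb by 0.37. By fry the adjusted p was 0.0537 for both lists and 0.0579 for ribosomal proteins, so 0 lists passed in one direction.

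Endothelial and mural markers were lower, with a median of -0.22 and 19 of 22 members negative (camera adjusted p = 0.000269; adjusted p = 0.536 with an estimated correlation). Igfbp7 differed by -0.79, Ly6a by -0.62 and the transporter Slco1a4 by -0.46, and 2 members passed adjusted over the list alone. The endothelial median was -0.14 without TG placebo replicate 3. Targets of Nrf2, a regulator of the antioxidant response, had a median of 0.16 (26 of 27 higher, camera adjusted p = 0.0068; adjusted p = 0.808 with an estimated correlation). Gstm1 differed by 0.50, Ftl1 by 0.35 and Hmox1 by 0.42, and 1 member passed adjusted over the list alone. Cholesterol synthesis genes had a median of -0.09 and immediate early genes one of 0.32, both with a camera adjusted p of 0.0335 and 0 members passing adjusted over the list alone. With an estimated correlation the adjusted p was 0.808 for both. Nsdhl differed by -0.33 and Dhcr7 by -0.28. Klf6 differed by 0.39 and Ier2 by 0.47, while Jun went the other way at -0.30. The camera calls of Nrf2 targets, cholesterol synthesis and immediate early genes also rested on single libraries. That of Nrf2 targets was lost without TG placebo replicate 2 (median 0.15, adjusted p = 0.0539) or replicate 3 (0.10, adjusted p = 0.116). That of cholesterol synthesis was lost without TG placebo replicate 2 (-0.04) or 3 (-0.05), or without NM-101 replicate 1 (-0.06) or 2 (-0.11), at an adjusted p from 0.122 to 0.148. That of immediate early genes was lost without TG placebo replicate 1 (0.18, adjusted p = 0.594), NM-101 replicate 1 (0.29, adjusted p = 0.140) or NM-101 replicate 3 (0.18, adjusted p = 0.225).

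**Figure D2:**
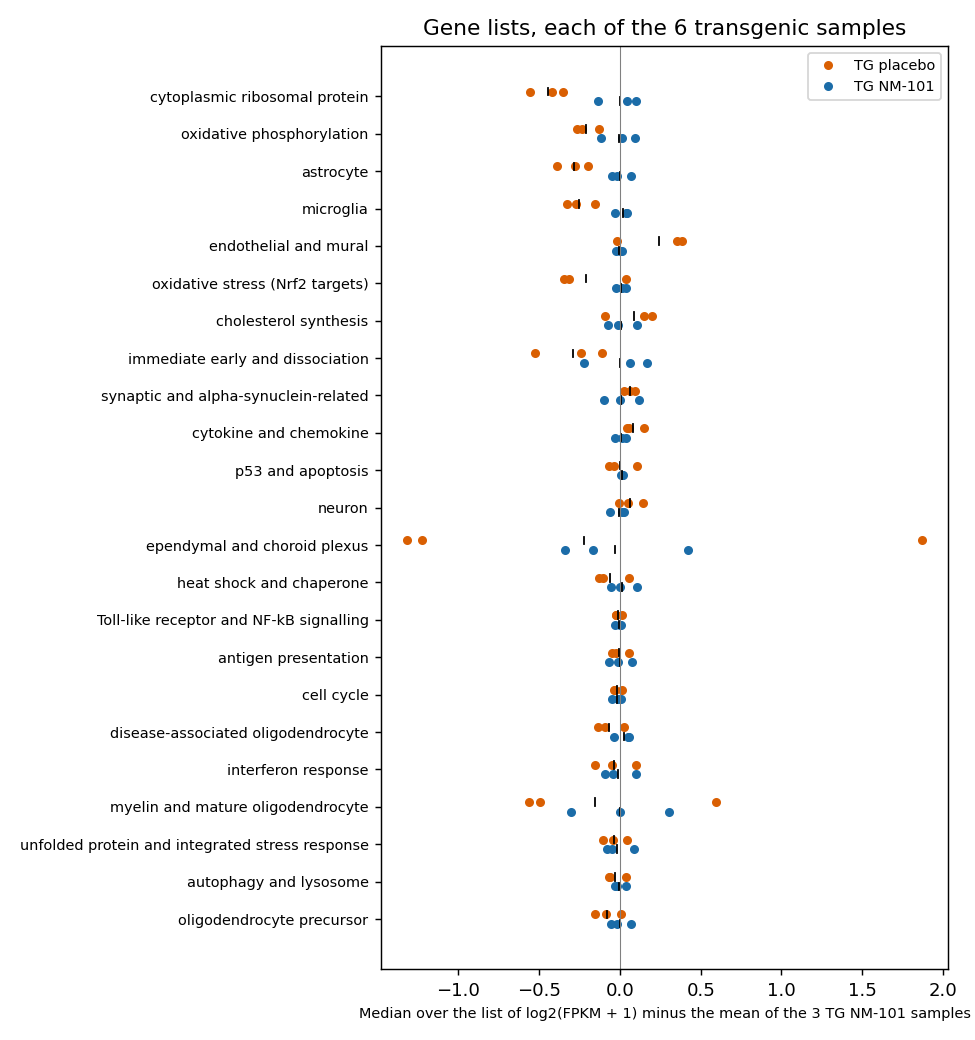
Each point is 1 sample's median over a gene list of log2(FPKM + 1) minus the mean of the TG NM-101 samples, with TG placebo in orange, TG NM-101 in blue and group means as black ticks. The ribosomal list separates the groups, while the ependymal and choroid plexus list spans -1.32 to 1.87 among the TG placebo samples.

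The groups closest to the study's subject did not pass. The myelin list had a median of 0.12 (camera adjusted p = 0.698), the oligodendrocyte precursor list 0.04, the disease-associated oligodendrocyte list 0.07 and the synaptic and alpha-synuclein-related list -0.08. The synaptic list passed by camera without NM-101 replicate 2, at -0.10 (adjusted p = 0.0141; adjusted p = 0.599 with an estimated correlation). The myelin gene Mbp was at 10.51 ± 0.96 under placebo and at 10.82 ± 0.45 under NM-101 (SD, n = 3). Olig2, a transcription factor of the oligodendrocyte lineage, was at 3.77 ± 0.30 and 3.80 ± 0.15, and Tlr2, a receptor of innate immunity, fell under the level tested, at 0.37 ± 0.16 and 0.60 ± 0.09 (SD, n = 3). The neuron list had a median of -0.05, autophagy and lysosome genes 0.05, heat shock genes 0.05, antigen presentation -0.004, cell cycle -0.01, p53 and apoptosis -0.04, cytokines and chemokines -0.05, and the ependymal and choroid plexus list 0.42. For 3 lists the signs of median, mean and test differed. Toll-like receptor and NF-kB genes had a median of 0.01 and a mean of -0.01, interferon response genes 0.03 and -0.01, and unfolded protein response genes -0.01 and 0.01.

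TG placebo replicate 1 differed from replicates 2 and 3 in some of these gene groups, and it was not always the unusual one. For endothelial and mural genes and Nrf2 targets it lay near the NM-101 mean, and replicates 2 and 3 did not. A further list, of 18 nuclear-retained RNAs, was set against the NM-101 mean too. It lay at -0.19 in replicate 1 and at 0.59 and 0.73 in replicates 2 and 3. TG placebo replicate 1 had a myelin list median 0.60 above the NM-101 mean, where replicates 2 and 3 lay at -0.49 and -0.56. For the ependymal and choroid plexus list the 3 values were 1.87, -1.32 and -1.22, for endothelial and mural genes -0.02, 0.36 and 0.39, for Nrf2 targets 0.04, -0.32 and -0.35, and for cholesterol synthesis genes -0.09, 0.15 and 0.20. Other groups kept 1 direction. The ribosomal list was below the NM-101 mean in all 3 placebo libraries, at -0.36, -0.55 and -0.42, as were the astrocyte list (-0.20, -0.28 and -0.39), the microglial list (-0.27, -0.15 and -0.33) and immediate early genes (-0.52, -0.24 and -0.11). The immediate early list did not separate the groups, as NM-101 replicate 2 lay at -0.22, below TG placebo replicate 3. Without replicate 1 the myelin list was called higher under NM-101 at a median of 0.52, the choroid list at 1.36 and heat shock genes at 0.11. The call of immediate early genes was lost, while the medians of cholesterol synthesis genes (-0.19), endothelial and mural genes (-0.39) and Nrf2 targets (0.33) grew and stayed called. With an estimated correlation none of these calls held, at an adjusted p of 0.682 for myelin, 0.446 for the choroid list, 0.726 for heat shock, 0.574 for cholesterol synthesis, and 0.385 for both endothelial genes and Nrf2 targets.

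The comparison of TG placebo with WT placebo asked what the genotype changed. The levels compared here were set across columns normalized separately, so no gene was tested and the values describe these libraries. Myelin genes had a median log2 difference of -0.35, at a percentile of 0 among matched random lists. The 3 TG placebo libraries lay at 0.34, -0.75 and -0.81 against the WT mean, so replicate 1 went the other way. The list stayed outside the matched range under 9 of 9 alternatives, at -0.75 without TG placebo replicate 1, -0.17 without replicate 2, -0.15 without replicate 3 and -0.55 without WT replicate 2. No alternative left out both replicates 2 and 3, the TG placebo libraries below the WT mean, which were also high in nuclear RNA. The alternatives therefore cannot show whether the value holds without them. The matched range does not allow for the correlation between members, estimated at 0.90 for the myelin list in the 6 TG samples. The other 5 lists outside that range did not stay there. Interferon response genes lay below every WT library in all 3 (-0.23, -0.39 and -0.25), with a list median of -0.16 at percentile 1.0, and were outside under 5 of 9 alternatives. They were not outside without WT replicate 2 (-0.06) or TG placebo replicate 2 (-0.09) or 3 (-0.14), or with single-transcript genes only (-0.11). Autophagy and lysosome genes lay above every WT library in all 3 (0.16, 0.13 and 0.12), with a median of 0.12 at percentile 98.1, outside under 4 of 9. They were not outside without WT replicate 3 (0.11) or TG placebo replicate 1 (0.12) or 3 (0.11), with single-transcript genes only (0.11) or with matching on level alone. Immediate early genes (median -0.15), endothelial and mural genes (-0.10) and microglial genes (-0.10) were also outside, which made 6 of 23 lists. They were outside under 7, 6 and 5 of 9 alternatives. The immediate early value was -0.04 without TG placebo replicate 1 and -0.08 without WT replicate 2, where it was not outside, and -0.26 without TG placebo replicate 3. The endothelial value turned to 0.06 without WT replicate 1 and to 0.03 without TG placebo replicate 1, and was -0.27 without WT replicate 3 and -0.03, not outside, with single-transcript genes only. The microglial medians of the 3 TG placebo libraries went both ways (-0.08, 0.09 and 0.0017), and the list was not outside without WT replicate 1 (-0.05) or TG placebo replicate 1 (-0.08) or 3 (-0.09), or with matching on level alone. The ribosomal, ependymal and choroid plexus, Nrf2 and p53 lists came outside when some single libraries were left out, the choroid list at -0.75 without TG placebo replicate 1 and at 0.78 without WT replicate 1. Rebuilt Mbp was at 11.12 ± 0.37, Olig2 at 3.67 ± 0.22 and Tlr2 at 0.45 ± 0.26 (SD, n = 3).

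For TG NM-101 against WT placebo the same description put 9 of 23 lists outside matched lists. Astrocyte markers were higher, with a median of 0.34 (0.45, 0.29 and 0.30 in the 3 libraries). Endothelial and mural genes were lower at -0.33 (-0.51 without WT replicate 3), and cholesterol synthesis genes at -0.15 (-0.08 without WT replicate 2), each with all 3 libraries below every WT library. Myelin genes were at -0.23, but the NM-101 libraries lay at 0.06, -0.56 and -0.26, so replicate 1 went the other way. The myelin value was -0.40 without NM-101 replicate 1, -0.07 without NM-101 replicate 2, -0.40 without WT replicate 2 and -0.14 without WT replicate 3. These 4 lists stayed outside under 9 of 9 alternatives, and the other 5 did not. Microglial markers, at 0.19, were outside under 4 of 9, and not without WT replicate 2 (0.13) or 3 (0.17) or NM-101 replicate 1 (0.14) or 3 (0.17), or with single-transcript genes only (0.23). Genes of p53 and apoptosis, at -0.12, were outside under 6, and not without WT replicate 2 (-0.08) or 3 (-0.06) or NM-101 replicate 2 (-0.08). Neuronal genes, at -0.08, were outside under 7, and not without WT replicate 2 (-0.04) or NM-101 replicate 2 (-0.07), and lay at -0.15 with median-ratio scaling. Interferon response genes, at -0.14, were outside under 6, and not without WT replicate 2 (-0.07) or NM-101 replicate 2 (-0.11) or with single-transcript genes only (-0.10), and lay at -0.23 without NM-101 replicate 1. Ependymal and choroid plexus genes were at 0.38, but this value rested on single libraries: it was 1.42 without WT replicate 1, -0.19 without WT replicate 2, -0.04 without WT replicate 3 and 0.01 without NM-101 replicate 2. It was 0.99 with single-transcript genes only. The ribosomal list, at 0.45, was at percentile 95.6 and so not outside, as matched lists had medians from 0.18 to 0.47, but it was outside without WT replicate 2, at 0.49. Without WT replicate 2 or NM-101 replicate 2 the immediate early list was outside too (0.28 and 0.20), as was the unfolded protein response list without WT replicate 1 (0.16) or NM-101 replicate 2 (0.15).

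**Figure D3:**
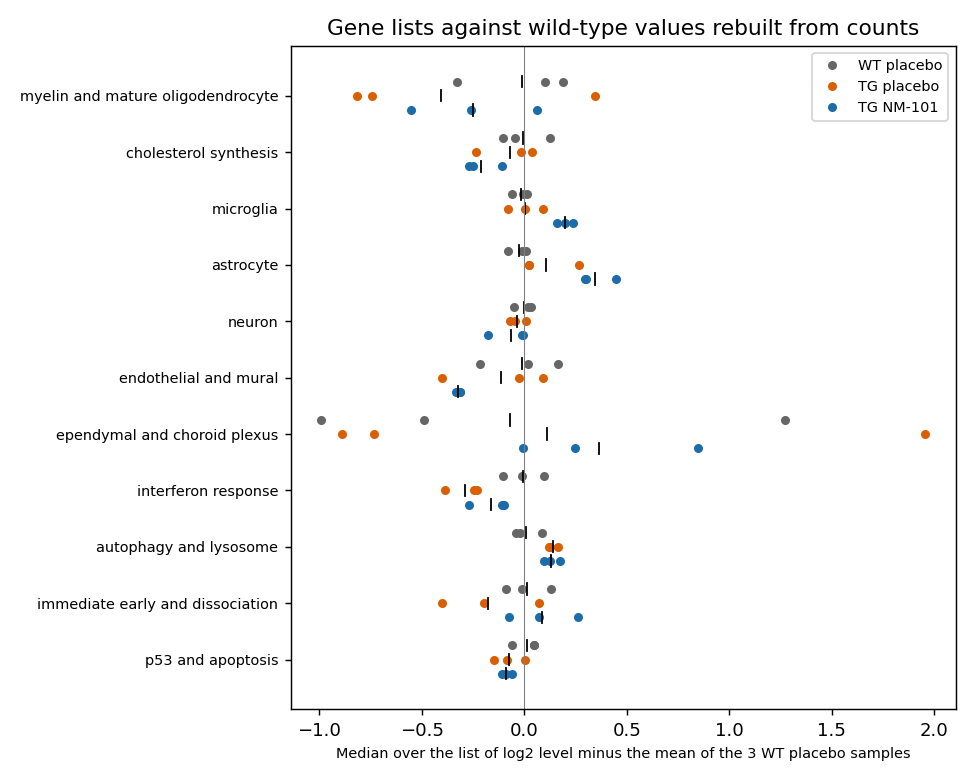
Each point is 1 sample's median over a gene list of the log2 level minus the mean of the WT placebo samples, whose values were rebuilt from counts, with WT in grey, TG placebo in orange, TG NM-101 in blue and group means as black ticks. The NM-101 samples lie above WT for astrocyte genes, at 0.29 to 0.45, and below WT for endothelial and mural genes.

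Whether NM-101 moved genes back towards WT was examined over 12410 genes. The TG placebo minus WT difference and the NM-101 minus TG placebo difference correlated across genes at -0.25, against -0.67 with no effect in simulations, and genes are not independent replicates. Both differences share the TG placebo samples, which alone gives a negative value. The simulations gave WT and TG samples the same mean per gene, so they left out any difference between rebuilt WT and deposited TG values. The TG placebo minus WT difference had an SD of 0.47 over genes, against 0.29 for NM-101 minus TG placebo. The gap between -0.25 and -0.67 therefore cannot be read as an effect of NM-101. The covariance was -0.0350, against -0.0311 ± 0.0032 (SD over 100 simulations) with no effect. The difference of -0.0039 was close to the SD of the simulations, in which genes varied independently. Its sign was not stable: it was 0.0016 with single-transcript genes only, -0.0769 without TG placebo replicate 1, 0.0371 without replicate 2 and 0.0311 without replicate 3, each against simulations of the genes and libraries kept. Without any 1 of the WT or NM-101 libraries it ran from -0.0077 to 0.00033. The correlation was -0.46 without TG placebo replicate 1, against -0.51 with no effect.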

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

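For TG NM-101 against TG placebo, the 17 gene calls changed with most settings, and the cause was not tested except where stated. Planned settings gave 4 calls with no filter on low values and 3 with the replicate block. After each group's mean was subtracted per gene, same-numbered TG placebo and NM-101 samples correlated at 0.06, -0.005 and -0.05. These values gave little sign that the numbers pair samples, but 3 samples per group cannot exclude it. The block left 8 lists called by camera at the preset correlation. With an estimated correlation it left 0, at camera adjusted p values of at least 0.812. Leaving out each sample gave between 2 and 2263 calls: 2263 without TG placebo replicate 1, 5 without replicate 2, 5 without replicate 3, and 2, 2 and 3 without NM-101 replicates 1, 2 and 3. Settings added after seeing the data gave 4 calls with median-ratio scaling, 127 with a mean of at least 10 FPKM, 4240 (2470 higher, 1770 lower) with limma array weights, 3 with a pseudocount of 10, 7 with RefSeq transcripts and 0 with only genes above 0 in all samples. The count with a pseudocount of 0.1 was 17. Keeping only genes above 0 in all samples ends the calls by construction in part, since it removes the zero-listed genes whose small p-values relax the adjustment.

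The 8 lists called fell to 0 with an estimated correlation and to 0 by fry in one direction, and ranged from 6 to 10 when each sample was left out. Of 587 values of named genes under alternatives, 7 had the other sign, none of them for a called gene. Of 364 list values, 29 lost a call, 7 gained one and 0 reversed. Besides those lost to left-out samples, an estimated correlation or fry, calls lost were that of cholesterol genes with no filter (camera adjusted p = 0.0698), of Nrf2 targets with a mean of at least 10 FPKM (0.162) and of immediate early genes with that mean (0.424) or array weights (0.0599). Calls gained were those of myelin (0.47) and choroid (0.99) genes with array weights and without TG placebo replicate 1, of heat shock genes without it, and of the synaptic list without NM-101 replicate 2 and with a mean of at least 10 FPKM (-0.08, camera adjusted p = 0.0217). With an estimated correlation the calls gained by leaving out a sample were lost, at camera adjusted p values of at least 0.446. The other gained calls were not retested that way. The correlation behind opposite changes was -0.25 (-0.67 with no effect), -0.17 with a mean of at least 10 FPKM (-0.67), and from -0.46 to -0.20 when each sample was left out. Simulations of the samples left in gave -0.51 with no effect beside the -0.46 without TG placebo replicate 1, and -0.79 beside the -0.20 without replicate 3. All of these simulated values leave out the difference of units between WT and TG. The lists outside matched lists ranged from 4 to 7 for TG placebo and from 6 to 10 for NM-101 against WT.

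DESeq2, its size factors in edgeR, voom weights and thinning were not run, because the TG columns hold no counts, and the planned tests against WT were not run because the units differ. Depth of the TG libraries is known only from the steps in their low values.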

Other observations

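The tests of the zero-listed genes, of TG placebo replicate 1, of the state of placebo replicates 2 and 3 and of the counts over other splits were chosen only after their results were seen. Ttr, the transthyretin of choroid plexus, was at 3573 CPM in WT replicate 1, 2.78 in replicate 2 and 19.9 in replicate 3. In TG placebo it was at 12.14, 2.65 and 3.60 on the log2(FPKM + 1) scale, and under NM-101 at 5.17, 9.998 and 5.96. By fry in either direction 4 lists passed, the astrocyte and microglial lists with an adjusted p of 0.00309 and the ribosomal and neuron lists with 0.0322.

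Of 9869 genes with all TG placebo values at 2 or more, 4 were listed at 0 in every NM-101 library. If values had been left out in processing, no other gene should sit just above 0, and 0 genes had a highest NM-101 value above 0 and under 1. The lowest highest value of any other of these genes was 1.62, so no gradient towards 0 was seen among them. NM-101 minus TG placebo differences had an SD of 0.29 over genes, so few could have fallen under 1 whatever the cause. The test therefore cannot tell values left out from loss of the RNA. Loss of these RNAs limited to the 4 genes stays open, because reads were not used here. For Rnu12 the 0 was not particular to NM-101, as it also had 0 counts in each WT library. A candidate explanation is that the 4 loci were not given an estimate in the NM-101 libraries.

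TG placebo replicate 1 correlated at 0.977 on average with the NM-101 libraries and at 0.960 with replicates 2 and 3, which correlated at 0.989 with each other. A swap with an NM-101 sample needs a partner. Each NM-101 library correlated better with the other NM-101 libraries than with replicates 2 and 3, by at least 0.0113. This cannot exclude a swap, because replicates 2 and 3 were also alike in their high nuclear RNA. A placebo sample without it need not resemble them. Replicate 1 was above 0 for all 4 zero-listed genes, but this follows from how they were picked and does not bear on a swap. Besides a swap, a pair of sources remain open together. A list of nuclear-retained RNAs (16 matched genes) was higher in replicates 2 and 3 by a median of 0.79 (percentile 100 among matched lists). Conversely, 18 ependymal and choroid plexus genes were higher in replicate 1 by 2.85 (percentile 100). Malat1, a nuclear RNA outside that list, was at 6.11, 9.00 and 9.48 in TG placebo replicates 1, 2 and 3. It was at 7.59, 7.65 and 7.09 under NM-101 and at 6.21, 5.27 and 6.13 in rebuilt WT values. Meg3 was at 4.77, 8.64 and 8.69 in TG placebo, 5.92, 5.87 and 5.23 under NM-101, and 6.37, 5.90 and 5.64 in WT. Replicates 2 and 3 were thus above every other library for both RNAs. RNA fraction and dissected tissue may both differ.

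Ribosomal protein genes were higher under NM-101 by a median of 0.45. Lists matched on level and length had medians from 0.16 to 0.31, so genes of like level and length also tended to be higher. The ribosomal list was at percentile 100 among them, and short transcripts may account for part of its median. Whether they account for all of it cannot be told from this percentile. The matched lists do not carry the correlation between ribosomal genes, estimated at 0.74. The state of placebo replicates 2 and 3 stays open. The difference from replicate 1 alone was 0.36, with an SD of 0.13 between NM-101 libraries. That is a single library, with choroid plexus genes higher than in replicates 2 and 3. As for NM-101 treatment, 1 of 10 splits of the 6 samples, the real one, gave a median as large in size. The largest other in size was -0.29. Treatment and an unrecorded technical difference between the groups cannot be told apart, since the labels give no batch.

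With 10 splits, a share under 0.05 is out of reach. The real split called 17 genes and the highest other split 1, so 1 split gave as many. The real split called 8 lists and the highest other 12, and 6 of the 10 splits gave at least 8.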
